A study of Mus musculus with 8 samples.

How the data were processed

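Gene expression was measured on 8 Affymetrix arrays, 1 per sample, in epithelial cells isolated from the small intestine of male ICR mice, an outbred stock, at 8 weeks of age. RNA was taken 4 days after nucleic acids had been introduced into the intestine of living mice. Per the labels, total RNA was turned into biotin-labelled material with the Affymetrix WT Terminal Labeling and Hybridization kit. The deposited values are intensity values on a linear scale, 1 per probe set and array, for 28853 probe sets. The background correction, the summarisation of probes into probe sets and the scaling behind these values are not given in the sources used here. The lowest value of each array lies just above 16, down to 16.0005, which is what a constant of about 16 added to all values would leave. Whether a constant was added was not tested; if so, log2 differences of dim genes are smaller than without it.

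The deposited intensities were put on the log2 scale. The medians of the 8 arrays then lay up to 0.32 apart, more than the limit of 0.2 set before the data were examined, so the arrays were quantile normalized, as laid down for that case. Centring each array on its 75th percentile and the deposited values without normalization were the alternatives. Of the probe sets, 23410 had a gene in the platform's annotation table. Among these, 21789 named 1 gene, 1621 named several genes and were not used, and 5443 further probe sets had no listed gene. Symbols were updated through Entrez identifiers for 21698 of the 21789 probe sets, from a RefSeq gene table of the GRCm38 assembly, and kept as annotated for the rest. No genome coordinates are given, because the assembly behind the probe sets is not given in the sources used here. Each of 19938 genes was represented by 1 probe set, the one with the highest mean over the 8 arrays. There were 999 genes with more than 1 probe set. No filter on dim genes was applied. For arrays, the number of samples limits the precision, and no depth applies. Members of gene families with similar sequences, such as the Cyp2j, Ugt2b, Ces2, Slc5a4, Gstm and defensin genes, can share array signal and are uncertain as single genes.

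Samples were grouped by their titles into siGFP (n = 3), siYAP/TAZ (n = 3), shLacZ (n = 1) and shYAP/TAZ (n = 1). The arrays labelled siYAP/TAZ were compared with the siGFP arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. The targeted genes were also tested with an exact two-sided permutation test. Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, two-sided and adjusted over the lists with 5 or more measured genes. The same lists were tested with an estimated correlation between genes and with fry, which asks whether the genes of a list move one way on balance. The shRNA arm has 1 array per group and no test. There the median of a list was placed among the medians of 10000 random lists of the same size matched on mean level in 20 bins. For the comparison over all 8 arrays, each array labelled as a knockdown was set against the control array that the labels assign to it, giving 3 siRNA comparisons and 1 shRNA comparison. The labels do not say what the arrays of such a comparison share.

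The lists covered YAP/TAZ target genes, Hippo pathway and TEAD genes, mitotic genes, DNA replication genes, stem cell markers, Wnt target genes, Notch target genes and regenerative and fetal-type epithelial genes. Others held markers of goblet, Paneth, enteroendocrine and tuft cells and enterocytes, and genes of the proximal small intestine, ileum and colon. Response lists covered interferon response, antigen presentation, mucosal defence and inflammation, p53 targets, the unfolded protein response, immediate early and heat shock genes, the circadian clock, PPAR and fatty acid oxidation, cholesterol synthesis and xenobiotic metabolism. Markers of T cells, B and plasma cells, myeloid cells, fibroblasts, smooth muscle, endothelium, erythroid cells, enteric neurons and glia, and genes of pancreatic enzymes stood for other cells in the isolate. The erythroid list had 1 measured gene and was not tested. A list of STAT3 response genes was added after the data were examined, before its values were looked at.

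Genes named in the text were chosen by a rule fixed before the data were examined. It takes Yap1 and Wwtr1, the 12 largest differences in each direction in the siRNA arm, up to 4 members of each list, the 5 largest differences in each direction in the shRNA arm among genes outside the dimmest 33%, and up to 10 genes per direction that differ one way in all 4 comparisons. In the siRNA arm the rule falls back, where no gene passes the threshold, on genes whose 3 arrays of one group all lie on one side of the other 3. Unnamed predicted genes, olfactory and vomeronasal receptors and antigen receptor segments are passed over for naming and kept in counts.

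The tests were checked on simulated data made with the real spread of the siRNA arm over 19938 genes. limma recovered 0% of 100 genes changed by 1 on the log2 scale, 30% of 50 genes changed by 2 and 72% of 50 genes changed by 3, and called 3 unchanged genes. In simulated data, camera called 3 of 3 lists raised by 1 on the log2 scale and 0 of the other lists. The simulated noise was independent between genes and the lists held random genes. The real lists hold genes that vary together, with an estimated correlation of 0.98 for mitotic genes. The simulation therefore does not show how many real lists camera calls wrongly. The alternatives tried were the normalization, leaving out the dimmest 33% or 50% of genes, averaging a gene's probe sets, an intensity trend with a robust prior, array weights (statmod 1.5.0), the replicate number as a block, both arms in 1 fit, leaving out each array, and fold limits of 1.3 and 2 in place of 1.5 over the 4 comparisons. Leaving out both arrays of one number, or one of the 4 comparisons, was added after the data were examined.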

Results

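YAP and TAZ are transcriptional coactivators restrained by the Hippo pathway, and TAZ is encoded by Wwtr1. The series asked what lowering both does to gene expression in the intestinal epithelium. In one arm, 3 arrays from intestine transfected with an siRNA against GFP, a jellyfish protein absent from normal mice, were the controls for 3 arrays labelled siYAP/TAZ. In the other arm, 1 array from intestine given a plasmid for an shRNA against bacterial LacZ was the control for 1 array labelled shYAP/TAZ. The labels do not tie the arrays of a group to separate mice, so p-values measure the spread between these samples, which may be technical. The median deposited intensity per array lay between 76.4 in siGFP 2 and 95.5 in shYAP/TAZ 1. Pearson's r between arrays over 19938 genes lay between 0.765 and 0.963, and no pair of arrays was identical. The first principal component held 56.8% of the variance and parted siYAP/TAZ 2, siGFP 3 and siYAP/TAZ 3, with scores of 64.5, 63.5 and 57.5, from the other arrays, with scores of -70.3 to -1.67, so the widest difference between arrays ran across the groups.

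The targeted genes were examined first. Yap1 had a mean log2 intensity of 7.33 ± 0.27 (SD, n = 3) in the siGFP arrays and 7.22 ± 0.38 (SD, n = 3) in the arrays labelled siYAP/TAZ. The log2 difference was -0.12 (SE 0.32, 95% confidence interval -0.84 to 0.61; exact two-sided permutation p = 0.8). Wwtr1 had 6.01 ± 0.59 (SD, n = 3) in the siGFP arrays and 5.73 ± 0.18 (SD, n = 3) in the arrays labelled siYAP/TAZ, a log2 difference of -0.28 (SE 0.36, 95% confidence interval -1.09 to 0.53; exact two-sided permutation p = 0.6). Neither gene was lower beyond the spread between arrays, and limma's adjusted p was 1.00 for both. The smallest p that 3 arrays against 3 allow in the exact test is 0.1. In each siRNA comparison one target was lower and the other higher: Yap1 differed by 0.25, -0.87 and 0.27 and Wwtr1 by -0.55, 0.58 and -0.86 on the log2 scale. In the shRNA comparison Yap1 differed by -0.09 and Wwtr1 by 0.06. By mean level over the 8 arrays, Yap1 stood at percentile 69.0 of all genes and Wwtr1 at percentile 30.4. Leaving out siGFP 2 or siYAP/TAZ 2 turned the Yap1 difference to 0.04 or 0.11. Because the targets were not measurably lower, the groups are called by their labels.

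**Figure D1:**
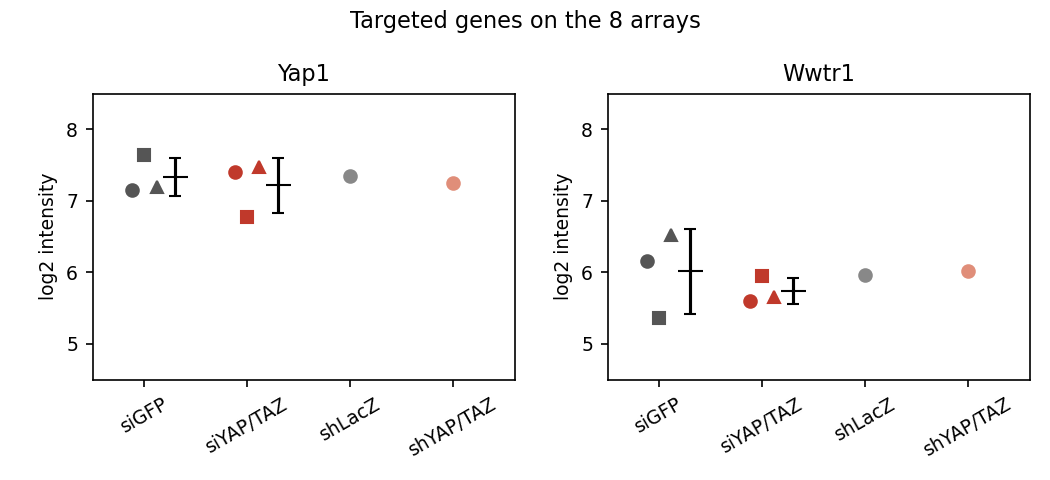
Log2 intensity of Yap1 and Wwtr1 (y axis) on each of the 8 arrays by group (x axis). Circles, squares and triangles are the arrays numbered 1, 2 and 3, and horizontal marks with bars give the mean and SD of the 3 arrays of an siRNA group. The groups overlap for both genes, with means of 7.33 and 7.22 for Yap1 and 6.01 and 5.73 for Wwtr1.

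In the siRNA arm, B3galt5, B3gnt7 and Socs3 were among the genes that stood highest in the arrays labelled siYAP/TAZ and Cubn, Apol10a and Rdh7 among those that stood lowest; none passed the threshold over all genes. B3galt5, a galactosyltransferase of glycan chains, was 7.05-fold higher in the mean, at 5.32 ± 0.44 (SD, n = 3) in siGFP and 8.14 ± 1.45 (SD, n = 3) in siYAP/TAZ. B3gnt7, which adds N-acetylglucosamine to such chains, was 6.27-fold higher, with a log2 difference of 2.65 (SE 0.65). Socs3, a feedback inhibitor of JAK-STAT signalling, was 4.15-fold higher, with a log2 difference of 2.05 (SE 0.41), and a second, dimmer probe set of the gene gave 0.59. Cubn, the gut receptor for vitamin B12 bound to intrinsic factor, was 7.19-fold lower in the mean, with a log2 difference of -2.85 (SE 0.99).

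All 3 siYAP/TAZ arrays lay above the 3 siGFP arrays for each further gene named as higher. The log2 differences were 2.21 for BC018473, 1.68 for Satb1, a chromatin organiser, 1.67 for Hk2, a hexokinase of glycolysis, and 1.66 for Ubd, a ubiquitin-like modifier. They were 1.62 for Chst4, a glycan sulfotransferase, 1.62 for Nudt5, 1.57 for Cyp4a12a, 1.55 for Ltf, which encodes lactoferrin, and 1.53 for Trim15. Satb1, Cyp4a12a and Ltf were dim in siGFP (mean log2 intensity 4.48, 4.51 and 4.55), so the size of their differences is uncertain. For the genes named as lower, all 3 siYAP/TAZ arrays lay below the siGFP arrays. Rdh7, a retinol dehydrogenase, was 5.47-fold lower, with a log2 difference of -2.45 (SE 0.44), and Apol10a was 5.49-fold lower, with a log2 difference of -2.46 (SE 0.61). The log2 differences were -1.90 for Slc5a4b, of the sodium and glucose transporter family, -1.63 for Hsd3b3, a steroid dehydrogenase, -1.56 for Ghr, the growth hormone receptor, and -1.55 for Fbp1, fructose bisphosphatase of gluconeogenesis. They were -1.48 for Cachd1, -1.46 for Slc6a20a, a proline transporter, -1.33 for Hpgd, which degrades prostaglandins, -1.32 for Ctdspl and -1.27 for Pmp22. Leaving out siYAP/TAZ 1 brought the log2 differences to 1.40 for BC018473, 0.97 for Hk2, 0.69 for Chst4, 0.95 for Cyp4a12a, 1.03 for Ltf, -1.56 for Cubn and -1.23 for Slc5a4b. Satb1 stood at 1.10 without siYAP/TAZ 2, Ubd at 0.92 without siYAP/TAZ 3 and Fbp1 at -0.71 without siGFP 2. In all, limma called 0 genes higher and 0 lower of 19938, with a smallest adjusted p of 1.00. At an unadjusted p under 0.05 there were 237 genes, 85 higher and 152 lower, fewer than the share of 0.05 of all genes that chance gives. Groups did not overlap for 916 genes, 319 higher and 597 lower, or 4.59% of genes, where chance gives 10%. A mean difference of at least 2-fold was seen for 127 genes higher and 85 lower. Of 7064 probe sets naming no gene or several genes, 0 passed and 169 had an unadjusted p under 0.05, again below that chance share of 0.05. The median residual SD of a gene was 0.42 on the log2 scale, and simulated changes of 1 on that scale were recovered for 0% of genes. Without siYAP/TAZ 1, limma called 11 genes higher and 2 lower, and 4 of the 11 belong to the 12 measured B and plasma cell markers (Cd22, Fcer2a, Ms4a1, Pax5). Without both arrays numbered 1, a choice made after the data were examined, it called 45 higher and 16 lower, with 8 of those 12 markers among the 45; Pax5 was named after its values were seen. Satb1 was also among the 11, and its differences of 0.42, 2.81 and 1.81 in the siRNA comparisons and -0.33 in the shRNA comparison lay beside B and plasma cell medians of 0.04, 2.75, 1.26 and -0.58.

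Of 34 gene lists, 9 passed camera's preset correlation in the siRNA arm, 3 lower and 6 higher, and 0 of them passed with an estimated correlation or with fry (smallest adjusted p of 0.424 and 0.900). Among the 10 ways to split these 6 arrays 3 against 3, 8 gave at least 9 lists, the real one included. No member of any list passed the threshold over all genes, and adjusted over the list alone 1 member passed, Socs3. That adjustment was made within each list and not over the 34 lists, and a second, dimmer probe set of Socs3 differed by 0.59. Stem cell markers of the crypt base fell as a list: all 18 measured members were lower in the mean, with a median log2 difference of -0.65 (camera adjusted p = 1.76e-05; adjusted p = 0.676 with an estimated correlation). Olfm4, at -1.76 (SE 0.93), and Lgr5, the receptor that marks cycling stem cells, at -1.45 (SE 0.81), were followed by Slc12a2 at -1.30 and Rgmb at -0.94. Olfm4 stood at -1.15 without siGFP 1, -1.11 without siYAP/TAZ 3 and -2.91 without siGFP 3. The stem cell medians of the 3 siRNA comparisons were -0.21, -1.63 and -0.16. In siRNA comparison 2, mitotic genes and Paneth cell markers had medians of -1.63 and -1.62. The call ended without siGFP 1 (median -0.23) or siYAP/TAZ 3 (median -0.23). The median was -0.35 without siGFP 2, -0.38 without siYAP/TAZ 2, -1.20 without siYAP/TAZ 1 and -1.22 without siGFP 3. Goblet cell markers fell as a list, with 20 of 24 lower in the mean and a median of -0.46 (camera adjusted p = 1.76e-05; adjusted p = 0.424 with an estimated correlation). Galnt12, Clca1 and Creb3l4 each stood at -0.73, while Retnlb, which the mucosal defence list also holds, stood at 1.55 (SE 1.65). The goblet medians of the siRNA comparisons were -0.59, 0.02 and -0.56. The goblet call ended without siYAP/TAZ 3 (median -0.25, adjusted p = 0.051), and without siGFP 1 the median was -0.22. Xenobiotic metabolism genes fell as a list, with 10 of 11 lower in the mean and a median of -0.87 (camera adjusted p = 0.00013; adjusted p = 0.424 with an estimated correlation). Ces2a, a carboxylesterase, was 4.01-fold lower in the mean, and Abcb1a, a drug efflux pump, stood at -1.37, Cyp2b10 at -1.08 and Cyp3a25 at -0.90. The xenobiotic call ended without siYAP/TAZ 1 (median -0.44) or siGFP 2 (median -0.05), and without siGFP 1 the median was -1.58.

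Mucosal defence and inflammation genes rose as a list in the siRNA arm, with 13 of 15 higher in the mean and a median of 1.07 (camera adjusted p = 4.54e-08; adjusted p = 0.424 with an estimated correlation). Lcn2, an iron-scavenging defence protein, stood at 1.76 (SE 1.42), the oxidase pair Duox2 and Duoxa2 at 1.66 and 1.57, and Nos2, the inducible nitric oxide synthase, at 1.65. Without siYAP/TAZ 1, Lcn2 turned to -0.31, Duoxa2 stood at 0.29 and Nos2 at 0.83; without siGFP 1, Duoxa2 stood at 2.89 and Nos2 at 2.96. Without siGFP 2 they stood at 0.93 and 0.77, and Duoxa2 at 0.90 without siGFP 3 and 2.67 without siYAP/TAZ 3. Lcn2 stood at 2.77 without siYAP/TAZ 2 and 2.81 without siYAP/TAZ 3. The medians of the siRNA comparisons were 1.97, 0.28 and 0.19, and the call ended without siYAP/TAZ 1 (median 0.29, adjusted p = 0.233). Antigen presentation genes rose as a list, with 11 of 12 higher in the mean and a median of 0.80 (camera adjusted p = 1.76e-05; adjusted p = 0.424 with an estimated correlation). H2-Aa stood at 1.20 (SE 0.97), Cd74 at 0.90, Psmb9 at 0.88 and Tap1 at 0.85. The antigen presentation medians were -0.25, 0.86 and 1.66, so siRNA comparison 1 ran the other way. The call ended without siGFP 3 (median 0.29, adjusted p = 0.107), and without siYAP/TAZ 3 the median was 0.36. Interferon response genes passed as higher, with 18 of 24 higher in the mean and a median of 0.14 (camera adjusted p = 0.000321; adjusted p = 0.747 with an estimated correlation). Ifit2 stood at 1.45 (SE 0.39), Usp18 at 1.25, Zbp1 at 1.25 and Dhx58 at 0.74. The interferon medians were -0.47, 1.24 and -0.10, so the siRNA comparisons did not share a direction. That call ended without siYAP/TAZ 3 (median 0.03), and the median turned to -0.06 without siGFP 2 and to -0.15 without siYAP/TAZ 2; without siGFP 1, siYAP/TAZ 1 or siGFP 3 it was 0.04, 0.75 or 0.64. B and plasma cell markers, which stand for lymphocytes in the isolate, rose as a list with 11 of 12 higher in the mean and a median of 1.43 (camera adjusted p = 2e-11; adjusted p = 0.424 with an estimated correlation). Cd22 stood at 1.94 (SE 0.96), Ms4a1, which encodes CD20, at 1.87, Fcer2a at 1.87 and Cd79b at 1.66. The B and plasma cell medians were 0.04, 2.75 and 1.26, and no single array ended the call, although the median was 0.77 without siYAP/TAZ 2 and 2.21 without siYAP/TAZ 1. Antigen presentation genes include class II genes that B cells also express. Unfolded protein response genes rose as a list, with 17 of 20 higher in the mean and a median of 0.22 (camera adjusted p = 0.000224; adjusted p = 0.424 with an estimated correlation). Chac1 stood at 1.28, Xbp1 at 0.81, Creld2 at 0.71 and Ddit3 at 0.69, and the medians of the siRNA comparisons were 0.58, 0.33 and -0.00. Without siYAP/TAZ 1 that call ended (median 0.09, adjusted p = 0.527), and without siGFP 1 or siYAP/TAZ 3 the median was 0.45 or 0.58. Immediate early and heat shock genes rose as a list, with 13 of 16 higher in the mean and a median of 0.26 (camera adjusted p = 0.00114; adjusted p = 0.424 with an estimated correlation). Socs3 passed over the list alone (limma, adjusted p = 0.0135; higher in 3 of 3 arrays), Ier3 stood at 0.65, Nr4a1 at 0.49 and Jun at -0.57. The immediate early medians were 0.44, 0.24 and -0.20, so siRNA comparison 3 ran the other way. This call ended without siGFP 1 (median 0.03) or siYAP/TAZ 1 (median 0.12), and the median was 0.08 without siYAP/TAZ 2 and 0.45 without siGFP 3.

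**Figure D2:**
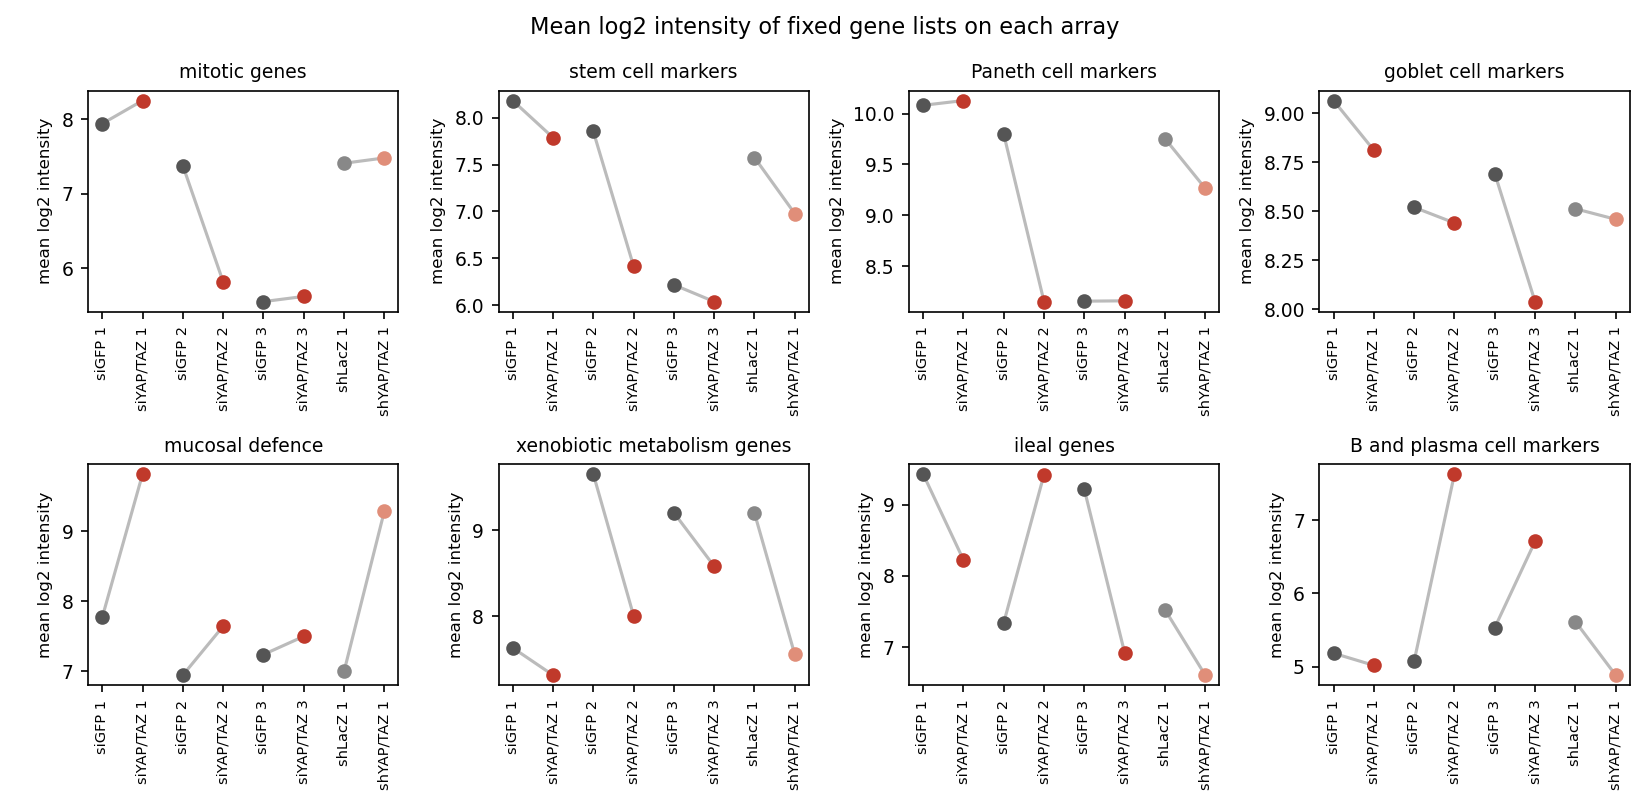
Mean log2 intensity (y axis) of the members of 8 gene lists on each array (x axis), with a line joining each array labelled as a knockdown to the control array that the labels assign to it. Grey points are controls and red points are arrays labelled siYAP/TAZ or shYAP/TAZ. The mitotic means run from 5.55 to 7.94 among the 3 siGFP arrays, and the B and plasma cell means of siYAP/TAZ 2 and siYAP/TAZ 3, 7.63 and 6.71, lie above the other arrays.

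The other 25 lists did not pass in the siRNA arm (camera). YAP/TAZ target genes, the list closest to the labelled treatment, had a median of 0.01 (adjusted p = 0.455), with 12 of 22 higher and 10 lower in the mean, and the sign turned to -0.05 without normalization. F3 stood at 0.53, Nt5e at -0.46, Crim1 at -0.39 and Gadd45a at 0.31. The YAP/TAZ target list passed as higher with array weights (median 0.27, adjusted p = 0.0389), without siYAP/TAZ 1 (median 0.25, adjusted p = 0.0296) and without siGFP 3 (median 0.22, adjusted p = 0.0344). Hippo pathway and TEAD genes had a median of -0.13 (adjusted p = 0.326; Amot -0.52, Lats1 -0.36). Mitotic genes had a median of -0.43 (adjusted p = 0.0588), with 22 of 24 lower in the mean, but their medians in the 3 siRNA comparisons were 0.30, -1.63 and -0.00. Ccnb2 stood at -0.76, Top2a at -0.72, Mki67 at -0.65 and Kif11 at -0.64. The mitotic list passed as lower with arrays centred on the 75th percentile (median -0.41, adjusted p = 0.027), with a trended robust prior (median -0.43, adjusted p = 0.0354) and with array weights (median -1.52, adjusted p = 3.76e-14). It also passed without siYAP/TAZ 1 (median -1.31) or siGFP 3 (median -1.16). DNA replication genes had a median of -0.15 (adjusted p = 0.232), with Ccne2, the cyclin E2 gene, at -1.06 (SE 0.32) and lower in all 3 siRNA comparisons. Wnt target genes had a median of -0.30 (adjusted p = 0.0903; Axin2 -0.90, Rnf43 -0.88) and Notch target genes one of -0.04 (adjusted p = 0.996; Dtx1 0.75). Paneth cell markers had a median of -0.69 (adjusted p = 0.0903; Pla2g2a -1.22, Ang4 -0.89, Lyz1 -0.76). Enteroendocrine markers had a median of -0.25 (adjusted p = 0.232; Nts -0.92), tuft cell markers 0.03 (adjusted p = 0.455; Plcg2 0.67) and enterocyte markers -0.21 (adjusted p = 0.232; Slc2a2 1.13, Lct -0.92). The tuft median turned to -0.02 without normalization. Regenerative and fetal-type genes had a median of 0.05 (adjusted p = 0.232; Il33 1.72). Along the gut axis the medians were 0.07 for proximal genes (adjusted p = 0.572; -0.00 without normalization), -0.26 for ileal genes (adjusted p = 0.23; Cubn -2.85, Mptx1 -0.94) and 0.13 for colonic genes (adjusted p = 0.23; Hoxb13 0.57).

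Among the response lists that did not pass, p53 target genes had a median of -0.12 (adjusted p = 0.232; Ei24 -0.69) and circadian clock genes one of -0.24 (adjusted p = 0.232; Dbp -0.69, Per3 -0.67). PPAR and fatty acid oxidation genes had a median of -0.37 (adjusted p = 0.0525; Pdk4 -1.28, Angptl4 -1.15). Cholesterol synthesis genes had a median of -0.22 (adjusted p = 0.0525), with 15 of 16 lower in the mean and Insig1 at -0.88. For other cell types, T cell markers had a median of 0.10 (adjusted p = 0.232; Ptprc 1.12), myeloid markers -0.17 (adjusted p = 0.787; Lyz2 -0.67) and fibroblast markers -0.16 (adjusted p = 0.0903; Fn1 -0.70). Smooth muscle markers had a median of 0.07 (adjusted p = 0.26; Lmod1 0.45) and endothelial markers one of -0.09 (adjusted p = 0.896; Pecam1 0.85). Enteric neuron and glia markers had a median of 0.20 (adjusted p = 0.131; S100b 0.57) and pancreatic enzyme genes one of -0.01 (adjusted p = 0.769; Clps -0.53). The measured erythroid gene, Alas2, stood at -0.29. With array weights, DNA replication (median -1.05), Wnt target (median -1.19), Paneth (median -1.58) and cholesterol synthesis genes (median -0.70) passed as lower. With arrays centred on the 75th percentile, Wnt target (median -0.30) and PPAR genes (median -0.37) passed as lower, the latter also with a trended robust prior. Tuft cell markers passed as higher without the dimmest 33% or 50% of genes (medians 0.31 and 0.38) and T cell markers without the dimmer 50% (median 0.30). Single arrays moved further lists past the threshold. Without siYAP/TAZ 1 or siGFP 3, DNA replication (medians -0.80 and -0.79), Wnt target (-0.84 and -1.04), Paneth (-1.21 and -1.26) and cholesterol synthesis genes (-0.84 and -0.35) passed as lower, and without siYAP/TAZ 1 enteroendocrine markers did too (-0.43). Ileal genes passed as lower without siGFP 2 (-0.71) or siYAP/TAZ 2 (-0.80), and cholesterol synthesis genes without siGFP 2 (-0.64). Enterocyte markers (-0.47 and -0.43) and PPAR genes (-0.35 and -0.41) passed as lower without siGFP 1 or siYAP/TAZ 3, circadian clock genes without siGFP 1 (-0.34), and fibroblast markers without siGFP 1 (-0.23) or siYAP/TAZ 2 (-0.19). T cell markers passed as higher without siGFP 1 (0.24), siYAP/TAZ 1 (0.27) or siGFP 2 (0.28). Leaving out both arrays of one number was chosen after the data were examined. T cell markers then passed as higher without number 1 (0.40) or 2 (0.28), but as lower without number 3 (-0.63). Their medians in the siRNA comparisons were -0.57, -0.65 and 1.05. Colonic genes passed as higher without siGFP 2 (0.27) and regenerative genes without siYAP/TAZ 2 (0.22) or siYAP/TAZ 3 (0.27). These p-values are camera's, and the other values are log2 differences between the means of 3 and 3 arrays.

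The shRNA arm compares 1 array labelled shYAP/TAZ with 1 shLacZ array, so its differences have no replicate check. Among genes outside the dimmest 33%, Lcn2 stood highest and differed by 6.28 on the log2 scale, Lrg1, an acute phase gene, by 5.81, Nos2 by 5.35, Fut2, a fucosyltransferase, by 4.26 and Saa3, a serum amyloid gene, by 4.08. Cubn stood lowest at -6.57, followed by Pmp22 at -5.20, Slc5a4b at -4.82, Trim30d at -4.13 and Gstm3, a glutathione transferase, at -3.98. Cubn and Trim30d were dim in shYAP/TAZ 1 (log2 intensity 4.37 and 4.47), so the size of their differences is uncertain. At least 2-fold differences were seen for 366 genes higher and 550 lower. Of the genes named in the siRNA arm, B3galt5 was 16.7-fold higher, Cyp4a12a 43.6-fold higher, Socs3 7.51-fold higher, Chst4 6.90-fold higher and B3gnt7 4.53-fold higher. The log2 intensity of Cyp4a12a was only 4.60 in shLacZ 1, so its fold is set against a dim value and is uncertain. Hk2 was 2.98-fold, Ltf 2.59-fold and Trim15 2.02-fold higher, with smaller log2 differences for Ubd (0.49) and Nudt5 (0.46), and values below 0 for BC018473 (-0.13) and Satb1 (-0.33). Hsd3b3 differed by -3.04, Rdh7 by -2.29, Slc6a20a by -1.60, Cachd1 by -1.52, Ghr by -1.31, Apol10a by -1.22, Fbp1 by -1.20, Hpgd by -0.87 and Ctdspl by -0.62.

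Of the 34 lists, 14 had an shRNA median outside the middle 95% of random lists, which describes this pair of arrays. The random lists hold genes drawn independently. Members of real lists vary together, with an estimated correlation in the siRNA arm of 0.78 for B and plasma cell markers. The percentiles can therefore overstate how far a list stands out. Mucosal defence and inflammation genes had a median log2 difference of 2.26 with 14 of 15 higher (percentile 100), cholesterol synthesis genes 0.81 with 14 of 16 higher (percentile 100) and myeloid markers 0.71 with all 15 higher (percentile 100). Among myeloid markers, Mpeg1 differed by 1.97 and Adgre1 by 1.43. Antigen presentation genes had a median of 0.47 (percentile 99.97) and tuft cell markers one of 0.21 (percentile 98.1). Xenobiotic metabolism genes had a median of -1.42 with 10 of 11 lower (percentile 0), B and plasma cell markers -0.58 with all 12 lower (percentile 0) and stem cell markers -0.46 with 16 of 18 lower (percentile 0.04). Lgr5 differed by -1.06 and Olfm4 by -1.90. Paneth cell markers had a median of -0.54 (percentile 0.54), circadian clock genes -0.40 (percentile 0.2), interferon response genes -0.39 (percentile 0.08), ileal genes -0.37 (percentile 2.42), Wnt target genes -0.35 (percentile 0.46) and enteroendocrine markers -0.22 (percentile 1.46). Mitotic genes had a median of 0.05 (percentile 79.9) and YAP/TAZ target genes one of 0.04 (percentile 74). With the deposited values or centring on the 75th percentile, tuft cell markers (percentile 96.9) and ileal genes (percentile 6.31) lay within the middle 95%.

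The siRNA and shRNA differences were set against each other across genes, which are not independent replicates. Over 19938 genes, Pearson's r between the mean siRNA difference and the shRNA difference was 0.424 and Spearman's rho 0.332, and 60.6% of genes had the same sign. Of the 200 genes with the largest absolute moderated t in the siRNA arm, among them B3galt5, Socs3, Rdh7 and Cachd1, 164 (82%) had the same sign in the shRNA arm, which has its own control array. The 3 siRNA comparisons taken singly gave r of 0.311, 0.334 and 0.037 with the shRNA comparison. Among themselves the siRNA comparisons gave r of -0.122 (1 and 2), 0.198 (1 and 3) and -0.104 (2 and 3).

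Across the 3 siRNA comparisons and the shRNA comparison, 67 genes differed at least 1.5-fold one way in all 4, 28 higher and 39 lower in the arrays labelled as knockdowns. B3galt5 had a mean log2 difference of 3.13 ± 1.03 (SD, n = 4), or 8.75-fold, Nos2 2.58 ± 2.15, B3gnt7 2.53 ± 0.28 and Tat, a tyrosine aminotransferase, 2.45 ± 1.86. The log2 intensity of Tat was 4.08 in shLacZ 1, 4.33 in siGFP 2 and 4.44 in siGFP 3, so its differences there are set against dim values. Socs3 had 2.27 ± 0.85, Duoxa2 1.93 ± 1.01, Chst4 1.91 ± 1.33, Tifa, an adaptor of NF-kB signalling, 1.79 ± 0.68, Slfn2 1.67 ± 0.61 and Hk2 1.65 ± 0.51. On the lower side, Cubn had -3.78 ± 2.54, Slc5a4b -2.63 ± 1.67, Rdh7 -2.41 ± 0.74, Pmp22 -2.26 ± 1.98 and Apol10a -2.15 ± 1.10. Ces2a had -2.07 ± 0.63, Hsd3b3 -1.99 ± 1.04, the stem cell marker Olfm4 -1.80 ± 0.71, Adgrd1 -1.75 ± 1.05 and Ghr -1.50 ± 0.26, each as SD over n = 4 comparisons. Among the fixed lists, mucosal defence genes were more frequent among the 28 higher genes than chance gives, with Nos2 and Duoxa2 of its 15 members (one-sided Fisher's exact test, adjusted p = 0.00671). Ileal genes were more frequent among the 39 lower genes, with Cubn and Mptx1 of 8 (one-sided Fisher's exact test, adjusted p = 0.00352), and the other lists did not pass. These tests were not among those fixed beforehand, rest on 2 genes each and take genes as independent. As a whole the ileal list had medians of -0.89, 1.64, -1.66 and -0.37 over the 4 comparisons and did not pass camera in the siRNA arm (adjusted p = 0.23). Exchanging knockdown and control within comparisons gave at most 37 genes in the other patterns; the 8 patterns are too few for a share under 0.05. Without normalization the count was 26 higher and 63 lower, and with 1 comparison left out, a choice made after the data were examined, it was 177, 201, 283 or 109 genes over the other 3 (without siRNA comparison 1, 2, 3 or the shRNA comparison).

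**Figure D3:**
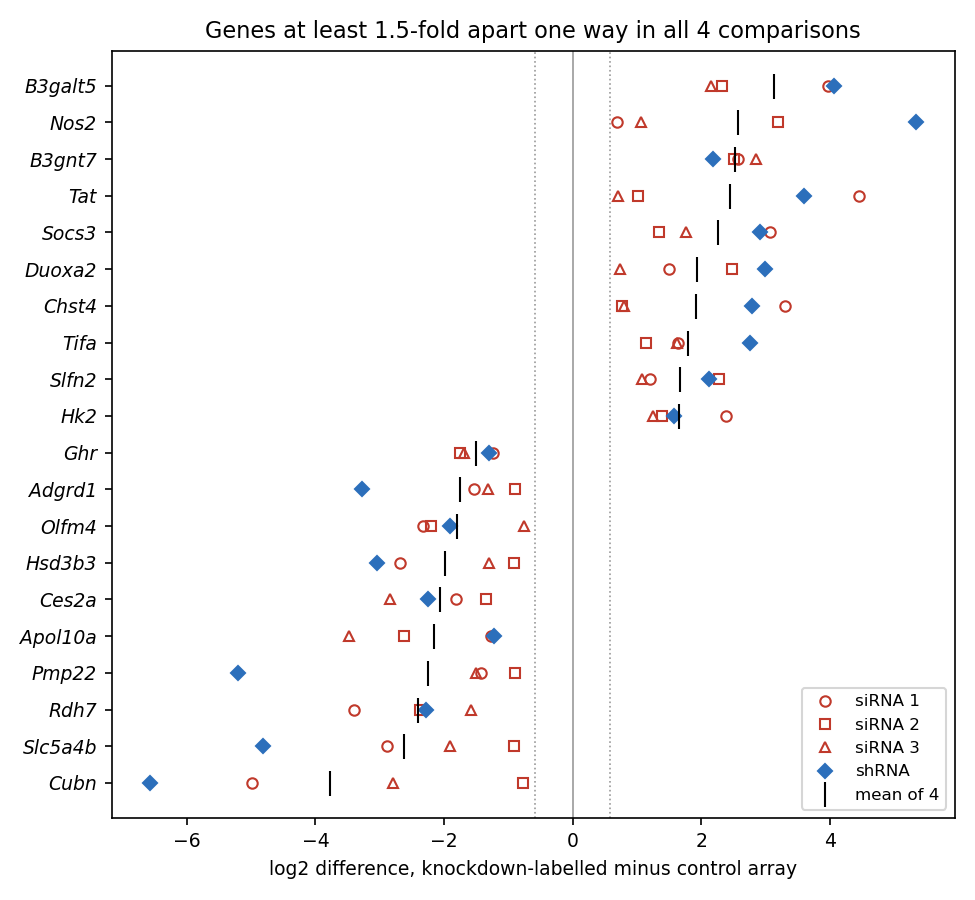
Log2 difference between the array labelled as a knockdown and its control array (x axis) for the 10 named genes per direction that differed at least 1.5-fold one way in all 4 comparisons (y axis). Open red symbols are the 3 siRNA comparisons, blue diamonds the shRNA comparison, black bars the mean of the 4, and dotted lines mark 1.5-fold. B3gnt7 varies little around 2.53 (SD 0.28), while Cubn runs from -6.57 to -0.76.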

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

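The results in this part were picked out after the data were examined, because all 3 siRNA comparisons lay on one side of 0 and the shRNA comparison on the other; none of these differences between the arms was tested. Cholesterol synthesis genes had a median log2 difference of 0.81 in the shRNA comparison against -0.03, -0.00 and -0.79 in the siRNA comparisons, of which the first 2 lie close to 0. B and plasma cell markers had -0.58 in the shRNA comparison against 0.04, 2.75 and 1.26 in the siRNA comparisons. BC018473 differed by -0.13 in the shRNA comparison against 4.99, 1.61 and 0.04 in the siRNA comparisons. Satb1 differed by -0.33 in the shRNA comparison against 0.42, 2.81 and 1.81 in the siRNA comparisons. As background, of 4437 genes with one sign in all 3 siRNA comparisons, 1450 (32.7%) had the opposite sign in the shRNA comparison.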

How the results depend on the processing

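Leaving out both arrays of one number, or one of the 4 comparisons, was chosen after the data were examined. The count of 0 genes past limma's threshold in each direction held under both other normalizations, both filters on dim genes, averaged probe sets, the trended prior, array weights and both arms in 1 fit. The shRNA lists outside the random range numbered 11 to 14, and the genes over the 4 comparisons 59 to 89, over normalizations, filters and probe set rules. Yap1 ran from -0.31 to 0.26 and Wwtr1 from -0.71 to 0.0121 when arrays were left out; Yap1 turned to 0.04 without siGFP 2, 0.11 without siYAP/TAZ 2 and 0.26 without both, and Wwtr1 to 0.0121 without both arrays numbered 3 and to 0.0213 with array weights. Genes higher ran from 0 to 45 and genes lower from 0 to 16, with both maxima without the arrays numbered 1. With the replicate number as a block, 1 gene was higher (B3gnt7, limma adjusted p = 0.0118) and 14 lists passed. Mitotic, Wnt target, Paneth, PPAR and cholesterol synthesis genes were among these lists, each as lower. Deviations from the group means correlated at 0.755, -0.13 and 0.571 for numbers 1, 2 and 3, and 3 of 6 arrays correlated best with their own number. The main limma and camera tests were planned without a term for the numbers and do not take them as pairs. The 4 comparisons do set each array against the control array that the labels assign to it. With both arms and a block for each of the 4 comparisons, 2 genes were higher (B3galt5, B3gnt7) and 2 lower (Rdh7, Olfr165). Olfr165 was named after its value was seen. In that fit mitotic, Wnt target, Paneth and circadian clock genes also passed as lower and enteric neuron and glia markers as higher, while interferon response genes did not pass. Lists past the threshold ran from 9 to 15 with arrays left out, were 8 to 12 over the other settings without a block and 13 with both arms and a block for each of the 4 comparisons, and were 0 with an estimated correlation and 0 with fry. The correlation between arms was 0.037 with siRNA comparison 3 alone. Genes over the 4 comparisons were 242 at 1.3-fold and 18 at 2-fold, and 109 to 283 with 1 comparison left out, where fewer conditions have to be met.

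Of 713 values of other named genes, 688 kept direction and side of the threshold, 17 passed it and 8 reversed. Lcn2 reversed to -0.0164 with array weights, -0.31 without siYAP/TAZ 1 and -0.37 without both arrays numbered 1, and was 2.82 without both numbered 3. Saa3 reversed to -0.37 without both arrays numbered 1 and was 2.12 without both numbered 3. Trim30d reversed to 0.39 with array weights and 0.21 without siYAP/TAZ 1, and was -1.61 without both arrays numbered 2. Gstm3 reversed to 0.25 without siGFP 2 and 0.31 without both arrays numbered 2, and was -1.40 without both numbered 3. The interferon median turned to -0.06 without siGFP 2, -0.15 without siYAP/TAZ 2 and -0.42 without both, and was 0.75 without siYAP/TAZ 1; both arms in 1 fit ended its call (median 0.06). Array weights ended the calls of mucosal defence genes (median 0.35), unfolded protein response genes (median 0.13) and immediate early genes (median 0.20). Apart from the counts with fewer comparisons, the cause was not tested.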

Other observations

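The tests in this part were chosen after the results were seen, except the splits of the 6 siRNA arrays and the STAT3 list, which was written after the data were examined and before its own values were looked at. Crypt genes varied between arrays more than between groups. Mean log2 intensity of the mitotic genes was 7.94, 7.37 and 5.55 in the siGFP arrays, 8.25, 5.82 and 5.62 in the siYAP/TAZ arrays, and 7.41 and 7.48 in shLacZ and shYAP/TAZ. Paneth cell markers followed, at 10.1, 9.80 and 8.16 in siGFP and 10.1, 8.15 and 8.16 in siYAP/TAZ. Interferon response genes stood the other way, at 9.18, 9.04 and 9.06 in siYAP/TAZ 2, siGFP 3 and siYAP/TAZ 3 and between 6.65 and 8.12 in the other 5 arrays. These 3 arrays are the ones that the first principal component set apart.

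Genes of the gut axis also differed between single arrays. Ileal genes averaged 9.43, 7.34 and 9.21 in siGFP and 8.23, 9.42 and 6.92 in siYAP/TAZ, with 7.53 in shLacZ and 6.61 in shYAP/TAZ. Slc10a2, the ileal bile acid transporter, differed by 0.72, 4.43 and -4.30 in the siRNA comparisons and by 1.98 in the shRNA comparison. Fabp1, a fatty acid binding protein of the proximal gut, differed by 4.96 in siRNA comparison 1 and by -2.54 in siRNA comparison 2.

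The crypt pattern was weighed against the share of crypt cells in the isolates. The knockdown alone is argued against as the source of the variation, since the mitotic means of the 3 siGFP arrays span 2.39 on the log2 scale, against a difference of -0.39 between the group means. For siGFP 2 against siYAP/TAZ 2, a smaller share of crypt cells in siYAP/TAZ 2 is a candidate explanation: the medians of mitotic, DNA replication, stem cell and Paneth genes were -1.63, -1.24, -1.63 and -1.62, within 0.398 of each other. Whether such a share alone accounts for the stem cell markers stays open, as does the labelled knockdown: their median minus the mitotic median was -0.52, -0.00, -0.15 and -0.51 over the 4 comparisons (mean -0.296, SE 0.129, n = 4, 95% interval -0.71 to 0.12). This interval takes the siRNA and shRNA comparisons as replicates of each other, although the arms differ in reagent and control array. Of the 10 splits of the 6 arrays, the real one gave 9 lists and the others 8 to 15. At least 9 lists were given by 8 of the 10, the real one included. The count of 9 lists therefore does not set the real groups apart from other splits. With 10 splits a share under 0.05 could not have been reached in any case.

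For the genes apart in all 4 comparisons, 1 of the 8 exchanges of labels reached 67, the real one, and the highest other gave 37, which is too few patterns for a share under 0.05. Immune cells in the isolate were weighed for the 28 higher genes. In siRNA comparison 1 the median of the 28 genes, 1.33, exceeded the -0.14 of T, B and myeloid markers by 1.47 (SD of the markers 0.53). In the shRNA comparison it was 1.57 against -0.03 (SD 0.83), with B and plasma cell markers at -0.58 and myeloid markers at 0.71. In siRNA comparisons 2 and 3 the gap lay within the SD of the markers (1.14 against 0.11 and 0.83 against 0.62). The 28 genes were chosen for passing 1.5-fold in each comparison, so part of each gap is built in and the test cannot decide. Immune markers did not rise as a set in siRNA comparison 1, where T, B and myeloid medians were -0.57, 0.04 and -0.10. Elsewhere immune cells stay open as a source, myeloid cells in the shRNA comparison among them. A STAT3-type response is a candidate explanation for a part. A separate list of 14 STAT3 response genes lay above the middle 95% of random lists in 3 of the 4 comparisons (medians 0.42, 0.08, 0.34 and 0.48). Without Fut2, which is also named above, left out after the data were seen, it was 3 of 4 as well. Random lists ignore that such genes vary together. Mucosal defence genes also had medians above 0 in all 4 comparisons (1.97, 0.28, 0.19 and 2.26), so the rank does not single out STAT3. This rank differs from the gap to the 28 genes used for the immune markers. That gap exceeded the STAT3 list's SD in siRNA comparison 3 (0.34 against 0.83, SD 0.45). Without Fut2 it did so in each comparison (medians 0.35, 0.04, 0.37 and 0.43, SD 0.90, 0.75, 0.44 and 0.51). Part of that gap is built in as well. For the 39 lower genes, a smaller share of enterocytes was weighed. The enterocyte medians were -0.48, -0.25, -0.09 and -0.06 over the 4 comparisons (SD 1.45, 0.93, 0.87 and 0.93). The 39 genes had -1.23, -0.96, -1.21 and -1.52. The gap exceeded the SD of the markers in siRNA comparison 3 and in the shRNA comparison. Since the 39 genes were chosen for passing 1.5-fold in each comparison, part of each gap is built in, and the test cannot decide. A smaller share of enterocytes stays open. A less ileal stretch of gut cannot be told apart. The ileal medians reach 1.64 in siRNA comparison 2 with an SD of 2.83 over 8 genes. Yet the list passes as lower without siGFP 2 or siYAP/TAZ 2 (medians -0.71 and -0.80). Cubn and Mptx1, 2 of its 8 genes, are among the 39 and so lower in each comparison by the way these were chosen. The labelled knockdown stays open.

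That Yap1 and Wwtr1 were not lower together was weighed against exchanged labels. In 0 of the 3 siRNA comparisons were both genes higher in the array labelled siYAP/TAZ. In 3 of 3 one of them was lower and the other higher by more than the SD of the 4 control arrays (0.22 for Yap1, 0.49 for Wwtr1). A difference between 2 arrays varies more than 1 array does, so spread between arrays can give this pattern under either labelling. The values therefore do not tell the labels as given from exchanged labels. Protein levels and the share of cells transfected were not analysed here. For the count of 0 genes past limma's threshold, that 10 of 10 splits gave as many was fixed beforehand, since none can give fewer, and says nothing about the groups; the highest other gave 4929, with siGFP 1, siYAP/TAZ 1 and siGFP 2 against the rest, which points to a structure of the samples other than the groups.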
